A study of Mus musculus with 10 samples.

How the data were processed

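Bulk RNA sequencing was carried out on osteoclast cultures grown from mouse bone marrow progenitors with M-CSF and RANKL, per the labels' protocols. The cultures were infected with Leishmania infantum amastigotes at a multiplicity of infection of 5 on day 2 of differentiation or left uninfected, and total RNA was taken 24 h after infection. The labels give 5 uninfected and 5 infected libraries from 3 mice, with 2 cultures per condition from mice 1 and 3 and 1 from mouse 2. Libraries are named here by mouse and culture number, so that uninfected 3-1 is the first uninfected culture of mouse 3.

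The authors deposited a table of read counts per gene, whole numbers that were not normalized, for 53700 genes. Reads had been aligned with HISAT2 2.0.5 to the mm10 genome build and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here, and the kit named in the labels does not by its name say whether strand was kept. Reads of overlapping genes on opposite strands could therefore not be told apart.

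The authors also deposited a table of 189 genes from their own comparison of infected with uninfected cultures. Per its file headers and values, it holds read counts, signal values that are the counts divided by 1 size factor per library, FPKM values, log2 fold changes and p-values with adjusted p-values, of which the largest is 0.0500. The tool behind the authors' log2 fold changes and p-values is not given in the sources used here. All 1890 count cells of that table equalled those of the count table exactly. The deposited FPKM values entered no test, and the deposited signal values served only to check that each library had a single scaling factor.

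The tests here started from the deposited counts in R 4.3.3. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 14983 genes. Libraries were scaled with TMM, dispersions were estimated robustly, and infected and uninfected libraries were compared with edgeR's quasi-likelihood test. P-values were adjusted with the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called changed. Every log2 fold change is infected minus uninfected, with the standard error of the fitted coefficient. Levels are CPM, read counts scaled to a common library total with the TMM factors, given as mean ± SD over the 5 libraries of a group. The fit without mouse was fixed as the reported one, and the fit with mouse as a block as its alternative, before the data were examined, as were the gene lists, the rule for named genes and the alternatives, apart from those said to be added later.

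The same replicate numbers in both groups stand for the same mice in the labels, so infected and uninfected libraries are paired by animal. Deviations from the group means also correlated within every number, at 0.292 for 1-1, 0.325 for 1-2, 0.441 for 2-1, 0.373 for 3-1 and 0.457 for 3-2. Each uninfected library correlated best with the infected library of its own number. In mouse 1 the other infected culture came close, at 0.276 for uninfected 1-1 and 0.258 for uninfected 1-2. Cultures of 1 mouse are not independent animals, and the fit without mouse leaves the pairing out. Its p-values therefore measure the spread between cultures with the spread between mice mixed into it. The 4 pairs of cultures of 1 mouse and condition differed by more than counting noise, with a chi-square per degree of freedom of 3.10 to 9.55 over genes with a summed count of at least 20, and each was kept as its own library.

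A second test asked whether the infection effect differed between mice, with an F test of both mouse-by-infection terms on 4 residual degrees of freedom. Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and adjustment over the lists. Of 42 fixed lists, 41 had at least 3 measured members. The adipocyte marker list had 2 measured members and 8147 reads in all, and was not tested. camera asks whether a list's genes rank above or below all other genes. fry asks whether they move, on balance, in 1 direction, and its mixed form whether they change in either direction, and neither compares the list with other genes. Counts of changed members are given over all genes tested and adjusted over the list alone. Measures with 1 value per library were compared with two-sided exact permutation tests over the 252 assignments of 5 and 5 libraries. These assignments leave out the pairing by mouse and take cultures of 1 mouse as independent.

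Named genes are the 12 largest increases and 12 largest decreases among called genes with the same sign in the 3 mice and an average log2 CPM of at least 1. Symbols that are only identifiers were left out. Only 5 decreases met the rule. Up to 4 members of each list with the smallest p and 10 osteoclast genes were added whatever their p, as were the 5 genes with the smallest p in the test between mice.

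Alternatives were other scalings (RLE, upper quartile, library totals), no filter, a filter of CPM of at least 1 in 5 libraries, DESeq2 1.42.0, limma-voom, mouse as a block, mouse and culture as a block, counts summed per mouse, other thresholds, each library left out in turn, each mouse left out in turn, and for the lists an estimated correlation and fry. Fits without uninfected 3-1 and infected 3-2, DESeq2 with mouse as a block, a DESeq2 likelihood ratio test between mice and fry with mouse as a block were added after seeing the data.

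The procedure was tested on simulated counts for the comparison of infected with uninfected cultures, drawn for 14983 genes from the observed means and library sizes. Of 50 genes changed by each fold size, 46% were recovered at the smallest, a log2 change of 0.32, and 58% were recovered at 1.5-fold, 82% at 2-fold and 96% at 4-fold, with 2 of 14766 unchanged genes called. With mouse as a block 54%, 60%, 84% and 98% were recovered and 13 unchanged genes were called. In the list test, a simulated 1.5-fold rise of the 18 neutrophil markers was recovered among 41 lists with no other list called. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera calls a list by chance when its genes move together.

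Gene locations are from the GENCODE M21 annotation of GRCm38 (mm10), matched by gene identifier. The coordinates in the deposited table were not used, because only 2.84% of the 52093 genes matched by identifier had the same start and end, while 98.3% had the same length. The build of those coordinates is not given in the sources used here. Of the 89 genes located for the text, 10 share over 10% of their exonic bases with another gene, and their values are uncertain to that extent.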

Results

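Gene expression was measured by RNA sequencing in osteoclasts, the multinucleated cells that resorb bone, grown from bone marrow progenitors of 3 mice. M-CSF and RANKL, which sustain macrophage-lineage cells and drive them to become osteoclasts, were in the medium. On day 2 of differentiation cultures received amastigotes of Leishmania infantum, the form of this protozoan parasite that lives inside macrophages, or were left uninfected, and RNA was taken 24 h later from 5 cultures per group. Libraries held 26617991 to 32146786 counted reads in uninfected and 23972016 to 30777308 in infected cultures (n = 5 each, two-sided exact permutation p = 0.389 for the means, smallest possible 0.00794). Between 21896 and 22668 genes had at least 1 read in a library. Mitochondrially encoded genes took 2.60 ± 0.169% of reads in uninfected and 2.58 ± 0.101% in infected cultures (SD, n = 5, two-sided exact permutation p = 0.857).

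The mouse of origin set the largest differences between libraries. Over the 14983 genes tested, mouse took a median of 27.9% of a gene's variance and infection 6.47%. Neither share is corrected for what chance gives with 10 libraries, which is more for 3 mice than for 2 conditions. The shares are therefore not effect sizes to be compared. The first 2 principal components, with 27.8% and 17.1% of the variance, separated the 3 mice. On the third component, with 14.1%, uninfected 3-1 lay at -24.9 and infected 3-2 at 19.5, while the other libraries lay between -8.61 and 11.2.

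**Figure D1:**
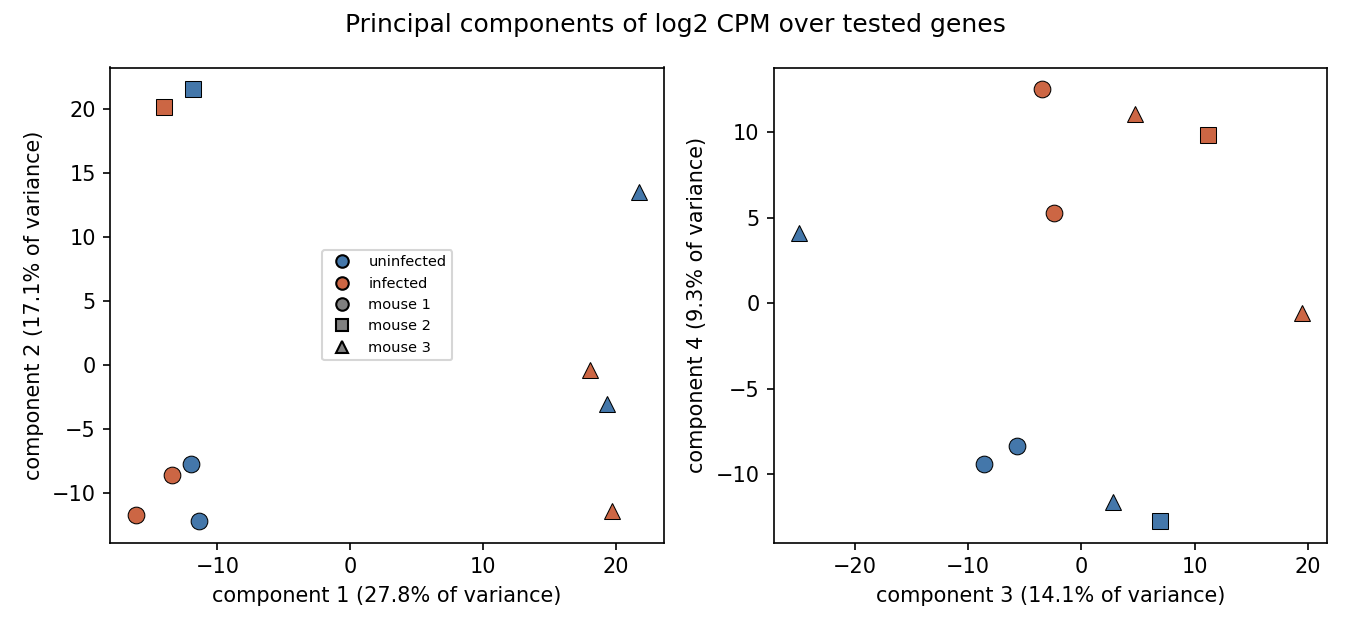
Principal components of log2 CPM over the 14983 tested genes, with components 1 and 2 on the left and 3 and 4 on the right; each point is a library, its colour the group and its shape the mouse. Components 1 and 2 (27.8% and 17.1% of variance) part the mice, and uninfected 3-1 (-24.9) and infected 3-2 (19.5) lie farthest out on component 3.

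The first comparison asked which transcripts differ between infected and uninfected osteoclast cultures. Ccr7, a chemokine receptor that guides mature dendritic cells to lymph nodes, rose from 1.64 ± 0.469 to 4.48 ± 0.372 CPM (SD, n = 5, log2 fold change 1.45 ± 0.17, SE, edgeR adjusted p = 0.00224). Ccl22, a chemokine that attracts T cells, rose from 2.79 ± 0.850 to 6.24 ± 1.39 CPM (log2 fold change 1.16 ± 0.20, edgeR adjusted p = 0.0200). Fscn1, an actin-bundling protein, rose from 2.62 ± 0.512 to 5.32 ± 0.951 CPM (1.03 ± 0.16, adjusted p = 0.00689). Gpnmb, an abundant membrane glycoprotein of macrophages and osteoclasts, rose from 1140 ± 141 to 1872 ± 170 CPM (log2 fold change 0.72 ± 0.08, edgeR adjusted p = 0.00283). Col4a1 and Col4a2 encode chains of type IV collagen, the network collagen of basement membranes. They fell together, Col4a1 by 0.59 ± 0.11 (adjusted p = 0.0309) and Col4a2 by 0.52 ± 0.07 on the log2 scale (adjusted p = 0.00283).

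In all, 72 of the 14983 genes changed, 67 upward and 5 downward, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each of the 72 moved in the same direction in all 5 pairs of infected and uninfected cultures, which is no separate support, as the same libraries gave the calls. Most changes were small: 8 genes changed at least 2-fold, and the median increase was 1.36-fold. In 298 genes, 1.99% of those tested, the groups did not overlap. Chance gives 0.794% for 10 exchangeable libraries, which libraries paired by mouse are not. The other 15 divisions that part all 5 pairs gave a median of 57 such genes and at most 111.

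The other named increases were Bhlhe41, a transcriptional repressor (log2 fold change 0.92 ± 0.17), Ms4a7, a membrane protein of macrophages (0.85 ± 0.13), Rgs1, which dampens G protein signalling (0.84 ± 0.16), Qpct, a glutaminyl cyclase (0.80 ± 0.11), F7, coagulation factor VII (0.76 ± 0.14), Il7r, the interleukin 7 receptor (0.67 ± 0.10), Arhgap22 (0.60 ± 0.11) and Aoah, which deacylates bacterial lipopolysaccharide (0.58 ± 0.11). Their edgeR adjusted p-values ran from 0.00425 for Qpct to 0.0326 for Rgs1. Ms4a7 rose from 9.72 ± 2.23 to 17.5 ± 1.41 CPM and Il7r from 6.83 ± 1.07 to 10.9 ± 0.720 CPM (SD, n = 5). The remaining named decreases were Gja1, the gap junction protein connexin 43, from 41.0 ± 4.47 to 28.2 ± 3.86 CPM (log2 fold change -0.54 ± 0.10, edgeR adjusted p = 0.0257), Gstt1, a glutathione transferase (-0.40 ± 0.06, adjusted p = 0.00369), and Cdk2ap2, which binds a cell cycle kinase (-0.25 ± 0.04, adjusted p = 0.00514).

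In GRCm38 (mm10), Ccr7 (ENSMUSG00000037944) lies on chromosome 11 at 99144196 to 99155077, Ccl22 (ENSMUSG00000031779) on chromosome 8 at 94745590 to 94751699, Fscn1 (ENSMUSG00000029581) on chromosome 5 at 142960343 to 142973185 and Gpnmb (ENSMUSG00000029816) on chromosome 6 at 49036546 to 49070929. Col4a1 (ENSMUSG00000031502), at 11198423 to 11312826 on the reverse strand of chromosome 8, and Col4a2 (ENSMUSG00000031503), at 11312805 to 11449287 on the forward strand, lie head to head. All are annotated as protein-coding genes in GENCODE M21. Of the named genes, Bhlhe41 shares 19% and Arhgap22 36.9% of exonic bases with another annotated gene.

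Genes chosen after their values were seen, because they fell under the level of the rule, were Apol7c (log2 fold change 2.19 ± 0.32, edgeR adjusted p = 0.00557), an apolipoprotein L family member, Nr4a3 (1.40 ± 0.25, adjusted p = 0.0195), a nuclear receptor, Cacnb3 (1.31 ± 0.20, adjusted p = 0.00717), a calcium channel subunit, and the long noncoding RNA AW112010 (1.11 ± 0.23, adjusted p = 0.0495). With the chemokine Ccl5 and the 3 named genes above 2-fold they make up the 8 genes. Apol7c rose from 0.486 ± 0.260 to 2.24 ± 0.624 CPM (SD, n = 5).

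With mouse as a block 211 genes changed, 189 upward and 22 downward, 71 of them among the 72, and DESeq2 called 188. The blocked count was 131 without uninfected 1-1, 133 without infected 3-1, 135 without infected 1-2 and 328 without uninfected 3-1. Without the block the count was 33 without infected 1-2, 41 without uninfected 3-2, 44 without uninfected 1-1 or infected 1-1, 46 without infected 3-2 and 140 without uninfected 2-1. Each of the genes below kept its direction when any 1 library was left out, but lost the call without some. They are 8 of the 17 genes named by size of change, together with Nr4a3 and AW112010. F7 lost it without uninfected 3-2, infected 1-1 or infected 3-2 (adjusted p up to 0.0596), Ccl22 and Nr4a3 without these or infected 1-2 (up to 0.0863 and 0.0714), and Gja1 without these 4 or uninfected 1-1 (up to 0.115). Col4a1 lost it without any of those 5 or infected 3-1 (up to 0.102), and Bhlhe41 without uninfected 1-1, uninfected 3-2, infected 1-2 or infected 2-1 (up to 0.0714). Aoah lost it without any library but uninfected 2-1, uninfected 3-1 and infected 3-1 (up to 0.102). Arhgap22 lost it without any but uninfected 2-1, uninfected 3-1 and infected 3-2 (up to 0.102), Rgs1 without any but uninfected 2-1 and 3-1 (up to 0.109). AW112010 lost it without any but uninfected 1-2 (up to 0.147) and with upper-quartile factors or library totals (0.0525 and 0.0608).

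**Figure D2:**
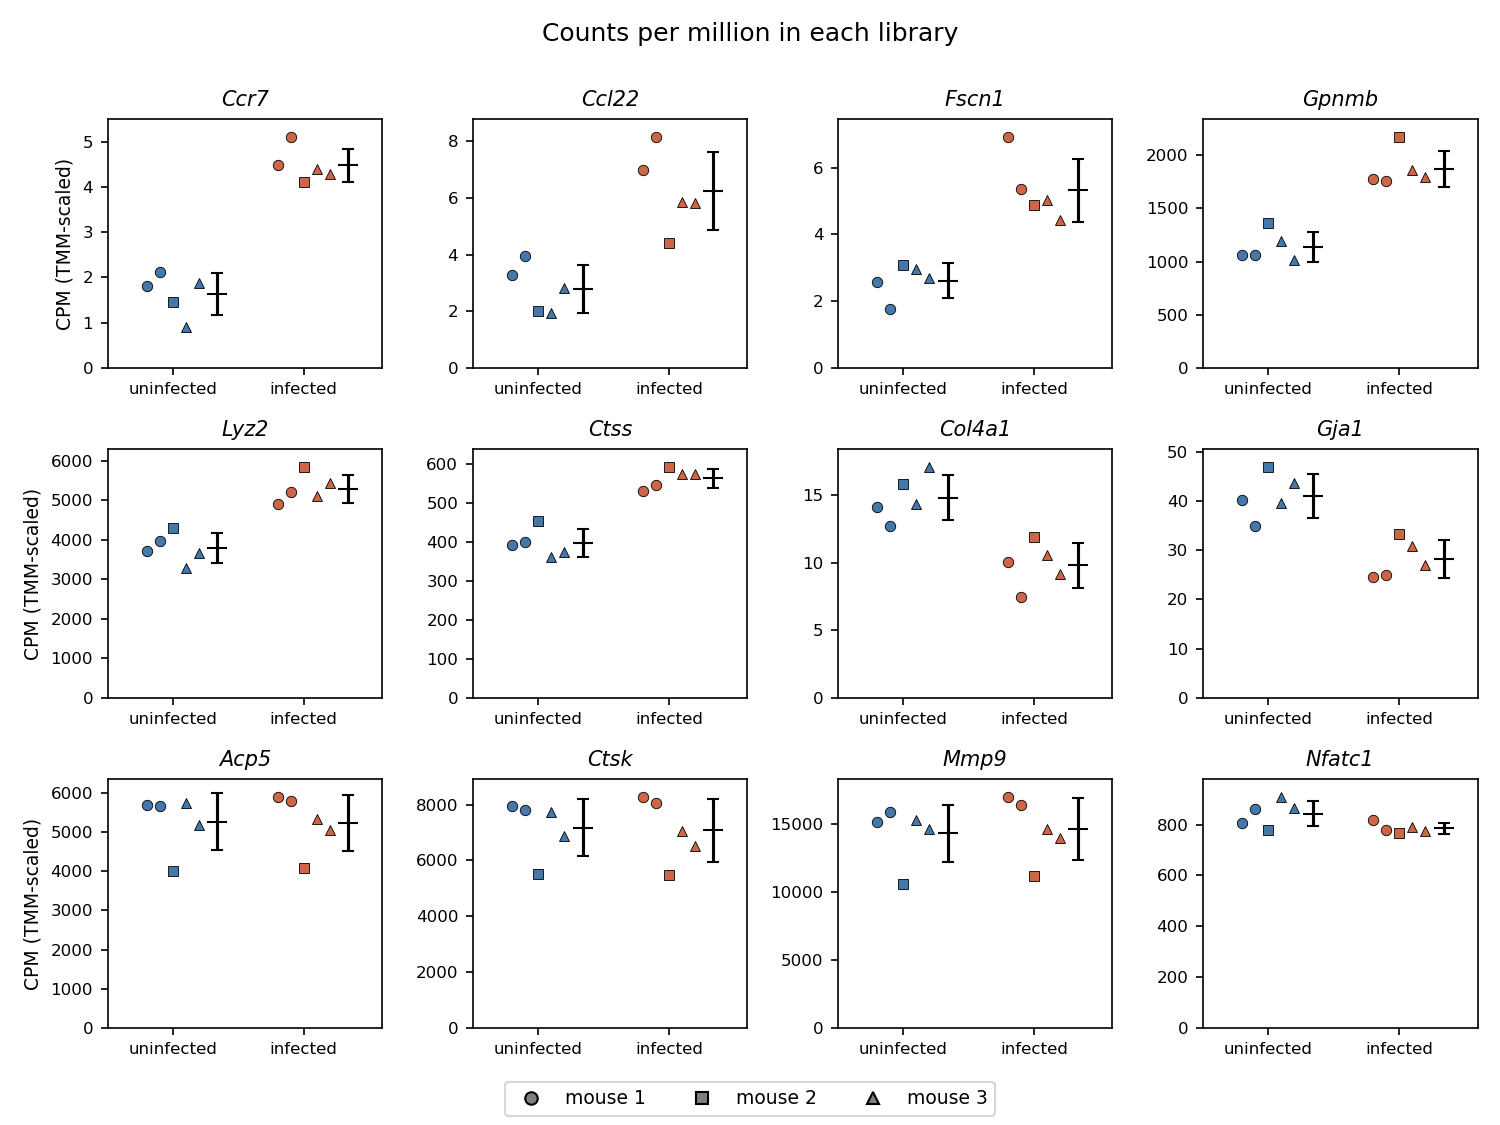
CPM of 12 genes in each library, in uninfected and infected cultures (5 each); marker shapes stand for the mice and bars for mean ± SD. Ccr7, Ccl22, Fscn1, Gpnmb, Lyz2 and Ctss are higher and Col4a1 and Gja1 lower in infected cultures, while Acp5, Ctsk, Mmp9 and Nfatc1 did not pass the test (adjusted p from 0.599 to 0.999).

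Osteoclast genes were examined next, as the measure of how far the cultures kept the osteoclast programme. None of the 10 genes fixed for this question passed edgeR's test, with adjusted p of 0.599 to 0.999. Acp5, tartrate-resistant acid phosphatase, was at 5265 ± 730.2 CPM in uninfected and 5232 ± 720 CPM in infected cultures (SD, n = 5, log2 fold change -0.01 ± 0.12). Ctsk, the collagen-degrading cathepsin K, was at 7175 ± 1018 and 7070 ± 1134 CPM (-0.02 ± 0.13), and Mmp9, the most abundant of the 10, at 14286 ± 2121 and 14619 ± 2294 CPM (0.03 ± 0.14). Nfatc1, the transcription factor that directs osteoclast formation, was at 843 ± 50.6 and 785 ± 20.8 CPM (-0.10 ± 0.04), lower in 4 of 5 pairs. Log2 fold changes of Calcr, Itgb3, Dcstamp, Ocstamp, Atp6v0d2 and Oscar ran from -0.08 to 0.02.

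Of the 29 measured genes of osteoclast differentiation and resorption, 0 passed edgeR's test over all genes, where DESeq2 called Trem2 (adjusted p = 0.00484). The count adjusted over the list alone was 1, also Trem2, a receptor of the DAP12 pathway (93.8 ± 13.4 to 119 ± 7.92 CPM, log2 fold change 0.34 ± 0.08), which passed with mouse as a block (edgeR adjusted p = 0.00159). The list's median log2 fold change was -0.015 and camera did not call it (adjusted p = 0.400). It was called lower without uninfected 2-1 (median -0.06, adjusted p = 0.00581) and without infected 1-1 (median -0.05, adjusted p = 0.0157). Acp5 (ENSMUSG00000001348) lies on chromosome 9 at 22126727 to 22135711 and Ctsk (ENSMUSG00000028111) on chromosome 3 at 95499256 to 95509362. Mmp9 (ENSMUSG00000017737) lies on chromosome 2 at 164940780 to 164955850 and Nfatc1 (ENSMUSG00000033016) on chromosome 18 at 80606205 to 80713071.

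Lists close to the resorbing machinery moved little. Of 18 V-ATPase subunits, which acidify the resorption pit and the lysosome, 1 rose, Atp6v0a1 (43.5 ± 4.96 to 54.5 ± 2.59 CPM, edgeR adjusted p = 0.0468), a call lost without any library but uninfected 2-1 (adjusted p up to 0.142) and with upper-quartile factors or library totals (0.0544 and 0.115). The list was not called by camera (adjusted p = 0.284, 1 member adjusted over the list alone), but was without uninfected 3-1 (0.0313), infected 2-1 (0.0216) or infected 3-2 (0.0461), and without both uninfected 3-1 and infected 3-2 (0.00367). None of 22 actin ring and podosome genes passed edgeR's test, over all genes or adjusted over the list alone (DESeq2 0, camera adjusted p = 0.811). Among 16 measured precursor fusion genes 0 passed by edgeR and 2 were higher adjusted over the list alone, with Cd81, a tetraspanin, at 17.4 ± 3.13 and 22.2 ± 2.47 CPM (edgeR adjusted p = 0.300, and 0.00094 with mouse as a block, higher in 5 of 5 pairs). The list's camera adjusted p was 0.0676, and 0.0345 with mouse as a block. Leaving out uninfected 1-1, 1-2 or 3-1 or infected 2-1 or 3-2 also brought it under 0.05, the lowest being 0.00576 without infected 2-1, and so did leaving out both uninfected 3-1 and infected 3-2 (0.0250). The 22 inputs of RANK and M-CSF signalling had 1 member higher adjusted over the list alone and a camera adjusted p of 0.0511, with 0.0156 under the mouse block and 0.00919 to 0.0487 without uninfected 1-1 or 1-2 or infected 2-1.

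Receptors that recognise microbes and macrophage genes had the smallest camera p-values of the lists. Of 28 pattern recognition and phagocytic receptors 6 rose, and 15 did so adjusted over the list alone. The 6 included the scavenger receptor Msr1 (97.1 ± 4.44 to 135 ± 9.36 CPM, log2 fold change 0.47 ± 0.05, edgeR adjusted p = 0.00106), the complement receptor C3ar1 (0.45 ± 0.07, adjusted p = 0.00903), Tlr1, which senses lipopeptides (0.45 ± 0.08, adjusted p = 0.0155), and the C-type lectin Clec4n (0.51 ± 0.09, adjusted p = 0.0155). The list's median log2 fold change was 0.32 and camera called it higher (adjusted p = 7.4e-18, adjusted p = 0.0504 with an estimated correlation). Of 20 macrophage and monocyte markers 4 rose, and 9 adjusted over the list alone, while 8 passed with mouse as a block. Among them were Lyz2, the macrophage lysozyme (3787 ± 382 to 5297 ± 354 CPM; 0.48 ± 0.07, edgeR adjusted p = 0.00438), and Cd14, a co-receptor for lipopolysaccharide (0.30 ± 0.05, adjusted p = 0.0183). Their median was 0.30 over all libraries and 0.19 without uninfected 3-1 (camera adjusted p = 5.61e-15, adjusted p = 0.0504 with an estimated correlation). The calls of Tlr1 and Clec4n were lost without infected 1-2 (adjusted p = 0.0509 and 0.0597), and that of Cd14 without uninfected 1-1, infected 1-2 or infected 3-1 (up to 0.0662).

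The summed level of the 20 macrophage markers was 7935 ± 508 CPM in uninfected and 9745 ± 296 CPM in infected cultures, higher in 5 of 5 pairs (SD, n = 5, two-sided exact permutation p = 0.00794, the smallest possible; 0.103 adjusted over 13 lists). The permutation leaves out the pairing by mouse, so its p-value does not measure the spread between animals. Most of the rise of the macrophage sum came from Lyz2, which alone went from 3787 to 5297 CPM. A sum without Lyz2 was not tested. The summed osteoclast genes were at 40875 ± 5080 and 41103 ± 5531 CPM (exact permutation p = 0.952). The other 11 sums had adjusted p-values of at least 0.486 by the exact permutation test. Of these, the neutrophil sum (1103 ± 107 and 1181 ± 75.3 CPM) and the dendritic cell sum (65.1 ± 13.3 and 75.8 ± 10.1 CPM) were also higher in 5 of 5 pairs.

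Chemokines and lysosomal genes had the next smallest camera p-values. Of 16 measured chemokines 3 rose and 6 adjusted over the list alone: Ccl22, Ccl5, which recruits T cells and monocytes (0.747 ± 0.214 to 2.09 ± 0.615 CPM, log2 fold change 1.48 ± 0.24, edgeR adjusted p = 0.0121), and Cxcl16, a membrane-bound chemokine and scavenger receptor (26.0 ± 2.49 to 34.4 ± 1.73 CPM; 0.41 ± 0.06, adjusted p = 0.00720; 18.3% of its exonic bases shared with another gene). All 16 had positive log2 fold changes with a median of 0.33 (camera adjusted p = 1.33e-10, adjusted p = 0.0504 with an estimated correlation). Of 28 lysosome and autophagy genes 3 rose, all cathepsins that degrade proteins, and 6 adjusted over the list alone, while 6 passed with mouse as a block. Ctss rose from 397 ± 36.0 to 564 ± 24.2 CPM (0.50 ± 0.06, edgeR adjusted p = 0.00129), Ctsb from 1926 ± 76.8 to 2422 ± 100.1 CPM (0.33 ± 0.04, adjusted p = 0.00224) and Ctsd from 977 ± 39.2 to 1139 ± 43.7 CPM (0.22 ± 0.04, adjusted p = 0.0180). Ctsb and Ctsd share 12.8% and 34.4% of their exonic bases with other genes, and Ctsd lost its call without uninfected 3-2, infected 1-2 or infected 3-1 (up to 0.0743). The lysosome list's median was 0.05 (camera adjusted p = 8.05e-09, adjusted p = 0.0553 with an estimated correlation), 0.030 without uninfected 2-1 and 0.084 without infected 2-1.

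Defence and signalling lists had few called members. Of 13 genes of MHC class I processing 1 rose, H2-K1, which presents peptides (470 ± 10.4 to 530 ± 16.3 CPM, edgeR adjusted p = 0.0334, lost with upper-quartile factors and library totals at 0.0521 and 0.0675 and without any library but uninfected 2-1 and infected 2-1, up to 0.123), and 4 adjusted over the list alone (camera adjusted p = 3.94e-08, adjusted p = 0.139 with an estimated correlation). With mouse as a block 3 of the 13 passed. B2m, its light chain, was at 624 ± 24.0 and 733 ± 55.2 CPM (adjusted p = 0.0588, and 0.000566 with mouse as a block). Of 22 NF-kB targets 2 rose, the feedback inhibitor Tnip3 (log2 fold change 0.31 ± 0.05, adjusted p = 0.00874) and the adhesion molecule Icam1 (0.21 ± 0.04, adjusted p = 0.0155), and 5 adjusted over the list alone. That list's camera adjusted p was 2.18e-06 (adjusted p = 0.139 with an estimated correlation), with a median of 0.053, and 0.034 without infected 1-1. Icam1, which shares 11.7% of its exonic bases, lost its call without uninfected 1-1, infected 1-1 or infected 1-2 (up to 0.0621).

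Of 16 genes of iron handling 1 rose, Slc11a1, the phagosomal metal transporter also known as Nramp1 (69.1 ± 6.75 to 93.5 ± 7.66 CPM; 0.44 ± 0.07, edgeR adjusted p = 0.0111, and 0.0521 without infected 1-2), and 2 adjusted over the list alone (camera adjusted p = 0.00375, adjusted p = 0.0553 with an estimated correlation). Of 21 matrix metalloproteinase and adhesion genes 1 rose, Mmp12, macrophage elastase (23.8 ± 3.17 to 35.4 ± 1.06 CPM; 0.57 ± 0.07, adjusted p = 0.00283). Adjusted over the list alone 4 were higher and 1 lower (camera adjusted p = 0.00017, adjusted p = 0.0504 with an estimated correlation). Their median was 0.069, 0.044 without uninfected 2-1 and 0.041 without infected 1-1. Of 20 measured oxidative stress genes 1 rose, Gstm1, a glutathione transferase (57.3 ± 4.38 to 75.1 ± 3.87 CPM; 0.39 ± 0.05, adjusted p = 0.00357), and 1 adjusted over the list alone (camera adjusted p = 0.00555, adjusted p = 0.298 with an estimated correlation). The oxidative stress median was 0.038, 0.062 without uninfected 2-1 and 0.075 without uninfected 3-1, and the call was lost without uninfected 3-2 (0.0771) and infected 2-1 (0.0728). None of 16 p53 targets passed edgeR's test, over all genes or adjusted over the list alone (DESeq2 0), yet all 16 had positive log2 fold changes (0.02 to 0.20, camera adjusted p = 0.000221, adjusted p = 0.0504 with an estimated correlation).

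**Figure D3:**
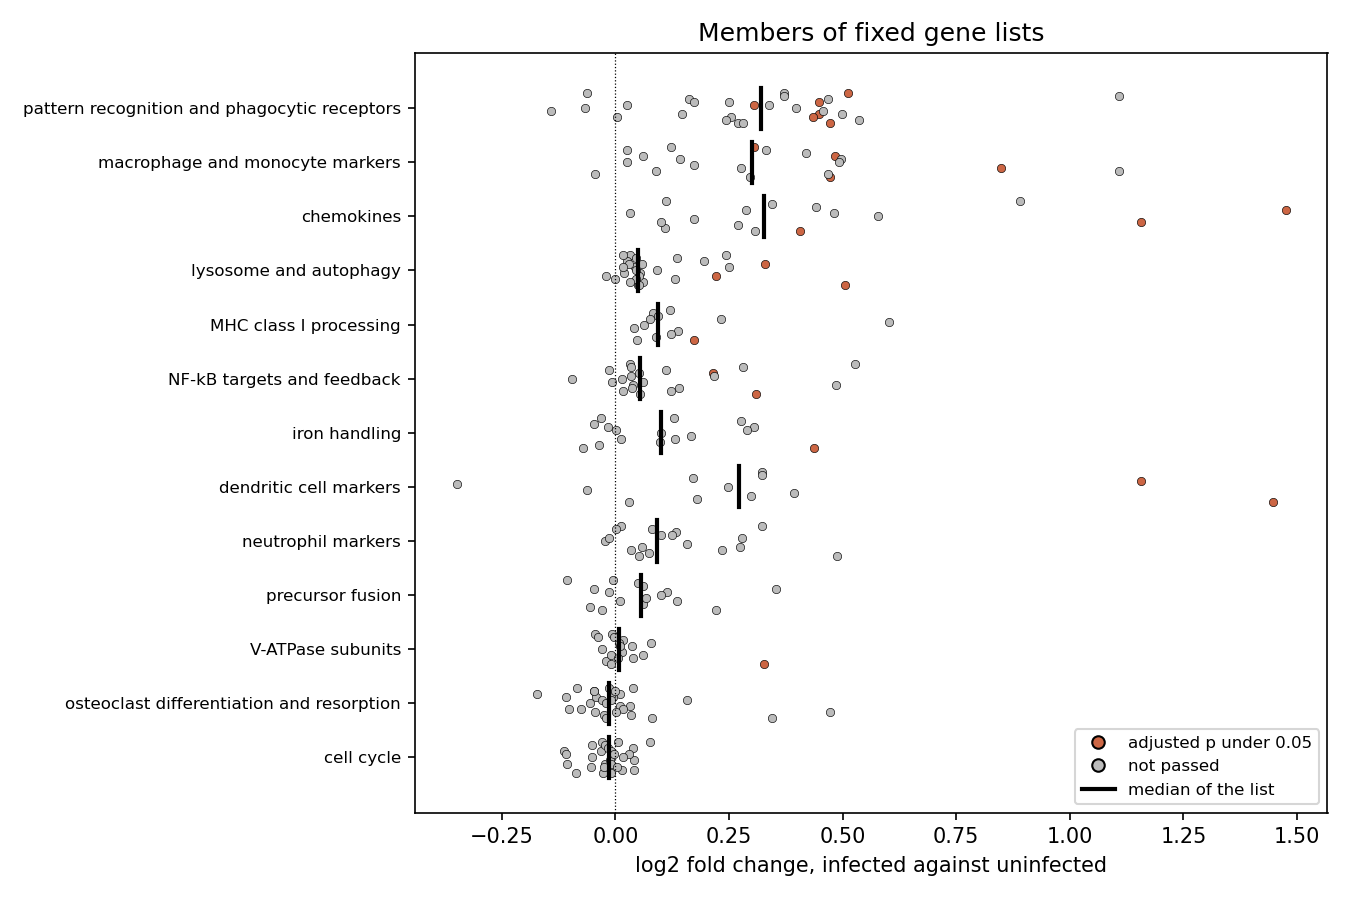
Log2 fold change (infected against uninfected) of each measured member of 13 gene lists; points are genes, coloured where the edgeR adjusted p is under 0.05, and black bars are list medians. Medians run from 0.33 for chemokines and 0.32 for pattern recognition receptors to -0.015 for osteoclast genes and for the cell cycle.

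The medians of 4 interferon and metabolic lists changed when single libraries were left out. No member of the 28 measured interferon-stimulated genes passed edgeR's test (Bst2, a membrane tether for virions, came closest over all genes, adjusted p = 0.0907, and 0.0333 with mouse as a block), and 1 was higher adjusted over the list alone. Their median was 0.18, 0.065 without uninfected 3-1 and 0.30 without uninfected 1-2 (camera adjusted p = 2.18e-06, adjusted p = 0.393 with an estimated correlation). The 20 measured genes of the interferon-gamma response and MHC class II had 0 calls over all genes or adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.00113, adjusted p = 0.456 with an estimated correlation). Without uninfected 3-1 that median was 0.067 and the call was lost (0.0900). Glycolysis and HIF1 targets, 24 genes with 0 calls either way, had a median of 0.13 and 0.049 without uninfected 3-1 (camera adjusted p = 2.21e-05, adjusted p = 0.406 with an estimated correlation). The 28 nuclear genes of oxidative phosphorylation, also with 0 calls either way, were the only list called lower (median -0.03, camera adjusted p = 0.0104, adjusted p = 0.701 with an estimated correlation), lost without uninfected 1-1 (0.0827), uninfected 3-1 (0.504), infected 2-1 (0.388) or infected 3-2 (0.180) and at -0.05 without uninfected 2-1. Without both uninfected 3-1 and infected 3-2 camera called none of these 4 lists: interferon-stimulated genes (median 0.062, adjusted p = 0.104), the interferon-gamma response (0.032, adjusted p = 0.741), glycolysis (0.051, adjusted p = 0.0521) and oxidative phosphorylation (0.0043, adjusted p = 0.727).

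Alternative activation genes, 18 measured, had 1 increase, Ccl22, and 2 adjusted over the list alone (median 0.20, 0.12 without uninfected 3-1 and 0.11 without infected 3-2, camera adjusted p = 9.09e-06, adjusted p = 0.128 with an estimated correlation). Mrc1, the mannose receptor, was at 44.7 ± 7.58 and 62.9 ± 7.68 CPM (adjusted p = 0.155, and 0.00119 with mouse as a block). The 19 measured negative regulators of osteoclastogenesis had 0 calls over all genes by edgeR and 6 higher adjusted over the list alone. Id1, a repressor of differentiation factors, was at 3.68 ± 0.727 and 5.36 ± 0.690 CPM and was called by DESeq2 (adjusted p = 0.0311), as was Lilrb4a (0.0397). Rbpj, the Notch transcription factor, passed with mouse as a block (edgeR adjusted p = 0.00938). The list was called higher (median 0.13, 0.087 without uninfected 3-1, camera adjusted p = 7.76e-05, adjusted p = 0.204 with an estimated correlation). Inflammatory cytokines, 16 measured, had 0 calls over all genes by edgeR and 2 higher adjusted over the list alone, while DESeq2 called Il1rn, an interleukin 1 antagonist (adjusted p = 0.00443), and Ebi3, a cytokine subunit (0.0107, and 0.0382 by edgeR with mouse as a block) (camera adjusted p = 0.00697, adjusted p = 0.317 with an estimated correlation). Their median of 0.12 was 0.072 without uninfected 3-1, 0.080 without infected 1-2, and 0.19 to 0.20 without uninfected 1-2, infected 2-1 or infected 3-1. Lipid efflux and LXR targets, 15 measured, had 0 calls by edgeR and 1 higher adjusted over the list alone, while Soat1, which esterifies cholesterol, was called by DESeq2 (adjusted p = 0.0112) and with mouse as a block (0.0320) (median 0.037, camera adjusted p = 0.0015, adjusted p = 0.0947 with an estimated correlation), with medians of 0.020 without uninfected 1-1 and 0.057 to 0.071 without uninfected 3-1, uninfected 3-2 or infected 1-2.

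Osteoclast-derived coupling factors, 13 measured, had 1 increase, Cxcl16, and 2 adjusted over the list alone (median 0.085, camera adjusted p = 0.0379, adjusted p = 0.388 with an estimated correlation). The call was lost without uninfected 2-1, uninfected 3-1, uninfected 3-2, infected 1-1 or infected 1-2 (0.0839 to 0.235), and the median was 0.050 without uninfected 1-2 and 0.033 without infected 3-2. It was also lost without both uninfected 3-1 and infected 3-2 (median 0.037, adjusted p = 0.0692). Igf1, a growth factor of this list, was at 18.4 ± 3.23 and 25.9 ± 4.31 CPM (edgeR adjusted p = 0.214, and 0.000399 with mouse as a block). Lists that camera did not call were cholesterol synthesis (adjusted p = 0.0620, and 0.0496 with mouse as a block), apoptosis regulators (0.112, and 0.0274), cell cycle (0.268), inflammasome and pyroptosis (0.318), the unfolded protein and integrated stress response (0.668) and polyamine and arginine metabolism (0.922). None of their members was called by edgeR, over all genes or adjusted over the list alone, and DESeq2 called 1, Ass1, an enzyme of arginine synthesis. Leaving out 1 library brought cholesterol synthesis (0.000988 to 0.0313 without uninfected 1-1, uninfected 3-1 or infected 3-2), apoptosis regulators (0.0239 and 0.0216 without uninfected 1-2 or infected 2-1) and the cell cycle (9.88e-05 to 0.0487 without uninfected 1-1, uninfected 1-2 or infected 2-1) under 0.05. Cholesterol synthesis was also under it without both uninfected 3-1 and infected 3-2 (0.000497).

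Markers of other bone marrow cells had few called members. Dendritic cell markers, 12 measured, had 2 increases over all genes and adjusted over the list alone, Ccr7 and Ccl22, with a median of 0.27, 0.14 without uninfected 3-1 and 0.17 without infected 3-2 (camera adjusted p = 0.000123, adjusted p = 0.317 with an estimated correlation). Zbtb46, a transcription factor of conventional dendritic cells, was at 3.66 ± 0.423 and 4.83 ± 0.954 CPM (adjusted p = 0.430). B cell and plasma cell markers (12 measured, median 0.39, 0.24 without infected 3-2, camera adjusted p = 0.000125, adjusted p = 0.343 with an estimated correlation), endothelial markers (6 measured, median 0.24, 0.15 without uninfected 3-1; 0.00742, adjusted p = 0.119 with an estimated correlation) and neutrophil markers (18 measured, median 0.091; 0.0048, adjusted p = 0.456 with an estimated correlation) were called higher by camera with 0 members called either way. The neutrophil call was lost without uninfected 3-1 (median 0.029, adjusted p = 0.1003) or infected 1-2 (0.121), and its median was 0.14 without infected 3-1. Without both uninfected 3-1 and infected 3-2 camera called none of these 4 lists, with medians of 0.063 for dendritic cell (adjusted p = 0.0802), 0.17 for B cell (0.123), 0.0905 for endothelial (0.0692) and 0.030 for neutrophil markers (0.170). Over all libraries fry called none of the 4 either (adjusted p = 0.234, 0.326, 0.0594 and 0.432 in the same order).

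camera did not call T and NK cell (adjusted p = 0.0873), mast cell and basophil (0.198), stromal and osteoblast (0.240), megakaryocyte and platelet (0.240), erythroid (0.513), mitochondrially encoded (0.268) or immediate early and handling stress genes (0.135). Adjusted over the list alone 1 immediate early gene was higher, and no other member of these lists passed. Each of these 7 was called without some single library, with adjusted p of 0.0031 to 0.0377: uninfected 1-1 for T and NK cells, infected 2-1 for mast cells, uninfected 2-1 or infected 1-2 for stroma, uninfected 1-2 for megakaryocytes, uninfected 3-1 for erythroid, uninfected 2-1 for mitochondrial and uninfected 1-2 or 2-1 for immediate early genes. Erythroid markers were called lower without both uninfected 3-1 and infected 3-2 (adjusted p = 0.0495).

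Altogether camera called 23 of 41 lists, 22 higher and 1 lower, and with an estimated correlation it called 0 (smallest adjusted p = 0.0504). Without both uninfected 3-1 and infected 3-2 it called 18, 14 of them among the 23. Of these 14, the median was then more than 1.5 times lower for pattern recognition receptors (0.17), macrophage markers (0.17), negative regulators (0.077), inflammatory cytokines (0.072), alternative activation (0.058) and MHC class I processing (0.049), and as much higher for oxidative stress (0.099) and lipid efflux (0.057). The fry test, which needs no preset correlation, called 7, all higher: pattern recognition receptors (0.0201), p53 targets (0.0201), iron handling (0.0201), chemokines (0.0239), lysosome (0.0254), macrophage markers (0.0276) and matrix metalloproteinases and adhesion (0.0276). With mouse as a block the count of called members also rose from 1 to 3 for alternative activation and from 1 to 2 for iron handling, matrix metalloproteinases and adhesion, oxidative stress and coupling factors. It went from 0 to 1 for RANK and M-CSF signalling inputs and for immediate early genes. Other divisions of the same 10 libraries into 5 and 5 gave a median of 14 and up to 29 camera calls, and a median of 0 and up to 5 fry calls.

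A further comparison asked whether the response to infection differed between the 3 mice. No gene passed edgeR's test of the mouse-by-infection terms (0 of 14983; smallest adjusted p = 0.962; 533 genes, 3.56%, at an unadjusted p under 0.05), while DESeq2's likelihood ratio test called 2. The genes with the smallest p by edgeR were Gm10076, Rsph3a, Gm10282, Maf, a macrophage transcription factor (log2 fold changes of 0.34, 0.18 and 0.78 in mice 1, 2 and 3), and Traf1, a signalling adaptor (0.30, 0.21 and -0.06). Ccr7 had log2 fold changes of 1.26, 1.45 and 1.67 in mice 1, 2 and 3, and Gpnmb of 0.74, 0.67 and 0.73. Over all genes tested the log2 fold changes of 2 mice correlated at 0.102 to 0.133 across genes, which are not independent replicates.

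The authors' deposited table lists 189 genes, 176 higher and 13 lower in infected cultures. All 72 genes called here are among them, with the same direction, and 153 of the 211 genes called with mouse as a block. In the authors' deposited table Gpnmb has the smallest adjusted p (2.3e-14), and Ctss and Msr1 have log2 fold changes of 0.50 and 0.47. A DESeq2 fit here gave 188 genes, each of them in the authors' deposited table, and log2 fold changes that differed from the deposited ones by at most 8.65e-07.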

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

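The test on the copies of Rpl17, and every search for libraries far from the rest of their group, were chosen only after the result was seen, as was the DESeq2 likelihood ratio test between mice. Of 244 groups of 5 libraries, 20 had a library far from the other 4 by Dixon's criterion, where chance gives about 1 in 20. Genes chosen after their values were seen are left out of this count. The far libraries were uninfected 3-1 with 7, uninfected 2-1 and infected 2-1 with 4 each, infected 3-2 with 2 and infected 1-1, 1-2 and 3-1 with 1 each. The rate of 1 in 20 is for independent libraries, while mouse 2 gave 1 culture to each group and mice 1 and 3 gave 2. A gene that differs in mouse 2 can therefore set its library apart in both groups.

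Some genes stood apart in the cultures of mouse 2. C1qa was at 28.3 CPM in uninfected 2-1 and 33.8 in infected 2-1, C1qb at 69.1 and 94.0, C1qc at 41.2 and 56.0, and Stab1, an endocytic receptor, at 172 and 220.4 CPM. These 4 genes were chosen after their values were seen. Cd81 was at 22.97 and 26.6 CPM in the same libraries. In uninfected 2-1, Trem2 (117 CPM) and C3ar1 (111 CPM) were highest and Mmp9 (10578 CPM) was lowest of the group. In infected 2-1, Gpnmb (2169 CPM) and the iron exporter Slc40a1 (23.3 CPM) were highest and Calcr (89.2 CPM) was lowest.

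Genes of the uninfected culture 3-1 stood apart as well. Its neutrophil collagenase Mmp8 (30.96 CPM) and Tlr1 (8.26 CPM) were lowest and its Il1rn, an interleukin 1 antagonist (37.5 CPM), was highest of the group. Its mean log2 CPM was lowest for glycolysis and HIF1 targets (6.87, the others 7.40 to 7.46), neutrophil markers (4.57), inflammasome genes (4.40) and alternative activation genes (2.31). Infected 3-2 was highest for inflammasome genes (4.84) and for Soat1, which esterifies cholesterol (156 CPM). Rgs1 was highest in infected 3-1 (3.48 CPM), C3ar1 lowest in infected 1-2 (115 CPM) and the proteasome subunit Psmb8 lowest in infected 1-1 (75.2 CPM). No explanation of these libraries was tested.

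For 2 genes the likelihood ratio test of DESeq2 called a difference of the infection effect between mice, while edgeR did not (adjusted p = 0.962 for both). They are the ribosomal protein gene Rpl17 (DESeq2 adjusted p = 2.2e-05), with log2 fold changes of -0.05, 1.70 and 0.26 in mice 1, 2 and 3, and Gm10076 (adjusted p = 5.96e-10), with -0.36, -1.49 and 0.82. Mouse 2 has 1 library per condition, so its values rest on a single pair and a difference between mice is not established. Rpl17 ran from 102 to 353 CPM over the libraries, while the sum over Rpl17 and its copies, 12 annotated genes in all, ran from 544 to 600.1 CPM. In mouse 2 that sum changed by -0.06 (-0.0568) on the log2 scale against 1.69 for Rpl17 alone. Reads shared between near-identical copies may therefore explain the change of Rpl17. A biological difference between the mice was not tested, and the copies of Gm10076 were not examined.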

How the results depend on the processing

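The fits without uninfected 3-1 and infected 3-2, DESeq2 with mouse as a block, the likelihood ratio test between mice and fry with mouse as a block were chosen only after the result was seen. The count of 72 changed genes stayed within 57 to 108 under RLE, upper-quartile and total scaling, a CPM filter and limma-voom with or without mouse as a random block. It was 113 without a filter, 188 by DESeq2, 211 with mouse as a block (131 to 328 when 1 library was left out), 407 with mouse and culture as a block, 268 by DESeq2 with mouse as a block, 27 at an adjusted p under 0.01 and 8 at 2-fold or more. Counts summed per mouse gave 8 genes without and 280 with the block. Leaving out 1 library gave 33 to 140 genes. Leaving out mouse 1, 2 or 3, which leaves fewer samples, gave 1, 116 and 15. Of these, 0, 64 and 13 were among the 72, and the 1 gene called without mouse 1 was a decrease. Without uninfected 3-1 and infected 3-2 the block fit gave 506. The test between mice gave 0 genes by edgeR and 2 by the DESeq2 likelihood ratio test. Called lists numbered 23, with 0 under an estimated correlation, 7 by fry, 14 by fry for mixed directions, 11 by fry with mouse as a block, 7 by fry and 18 by camera without uninfected 3-1 and infected 3-2, and 21 to 29 when 1 library was left out. The overlap with the deposited genes was 72, and 188 by DESeq2 and 153 with mouse as a block. Nuclear genes of oxidative phosphorylation reversed, with a median of 0.0043 by camera and by fry without uninfected 3-1 and infected 3-2 (adjusted p = 0.727 and 0.932). Apart from the calls given beside the results, the mouse block changed no other camera call of a list. It added fry calls for MHC class I processing (adjusted p = 0.0225), NF-kB targets (0.0225), lipid efflux (0.0101) and coupling factors (0.0207), and raised the mixed calls from 14 to 21. The cause of these differences was not tested. Depth limits genes such as Nr4a3, at 0.441 CPM in uninfected cultures.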

Other observations

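Among these tests, those on the macrophage markers, on dendritic cell identity genes and on other divisions of the libraries by genes or camera lists were chosen only after the result was seen. Macrophage and monocyte markers were higher in infected cultures while osteoclast genes were level. Within pairs the macrophage markers rose more than the neutrophil markers by a mean log2 difference of 0.19 (0.1938, SD 0.107, above 0 in 5 of 5 pairs, lowest 0.0162). They also rose more than megakaryocyte (0.27, SD 0.109) and erythroid markers (0.45, SD 0.259). The difference was within its SD for endothelial (0.09, SD 0.122), mast cell (0.13, SD 0.240) and stromal markers (0.2205, SD 0.2216). The macrophage list was chosen after its rise was seen, so these differences cannot decide about a lower share of osteoclasts. Mean log2 changes of B cell (0.34) and T and NK cell markers (0.32) were close to that of macrophage markers (0.34). That closeness goes with such a lower share. The summed T and NK cell markers were at 26.9 CPM in uninfected and 26.2 CPM in infected cultures, higher in 1 of 5 pairs. That sum was mostly its member Cd5 (22.04 of 29.16 CPM in uninfected 1-2), which was lower in the infected culture of each pair. Of the 7 measured T and NK cell markers, 5 had positive log2 fold changes. A sum without Cd5 was not tested, so the T and NK cell sum cannot decide about a lower share. Dendritic cell markers changed by 0.36 with Ccr7 and Ccl22 among them, and the identity genes alone by 0.17. A lower share stays open as the whole or a part of the cause. The median without uninfected 3-1 was 0.1871, against 0.30 over all libraries, which argues against that library as the whole cause. Of the 20 measured markers 19, or 95%, had positive log2 fold changes, which follows from the rise of the list itself, so more macrophages or monocytes and a change of expression within the same cells cannot be told apart.

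Ccr7, Ccl22, Fscn1, Apol7c, Ccl5, Cacnb3 and Nr4a3, genes of mature dendritic cells chosen after their values were seen, rose by a mean of 1.38 log2 units over the pairs. The 10 dendritic cell identity genes, which were not chosen by their change, had a mean log2 change of 0.17 (SD 0.261 over the pairs), and edgeR called 0 of them (1 at an unadjusted p under 0.05). By pair the identity genes changed by -0.0107 (1-1), -0.0661 (1-2), 0.0363 (2-1), 0.4728 (3-1) and 0.4413 (3-2). The 7 genes rose by more in each pair, with a mean difference of 1.21 (1.2082, SD 0.322, lowest pair 0.846). Their choice after their rise was seen raises that difference. It therefore cannot decide whether dendritic cells of every kind rose. The median of 22 further maturation genes, 0.07, lay at percentile 99.8 of 10000 random lists matched on expression, with 19 positive, 0 called by edgeR and 5 at an unadjusted p under 0.05. Genes of random lists need not move together as maturation genes may, and the percentile does not measure the spread between cultures. Whether a maturation programme extends beyond the 7 genes therefore stays open.

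Other divisions of the 10 libraries into 5 and 5 tested whether chance gives as many calls. Of 100 divisions, which are not all that are possible, 2 gave at least 72 genes, the real one included. The highest other count was 90, for all 4 libraries of mouse 1 with uninfected 3-1, which follows the mice. Shares of these 100 divisions take the libraries as exchangeable, which libraries paired by mouse are not. They therefore cannot exclude chance at the share of 1 in 20. With mouse as a block 1 of 36 balanced divisions gave at least 211 genes, the real one, and the highest other count was 31. For lists called by camera 11 of 100 divisions gave at least 23, with up to 29, so chance could not be excluded, while for fry 1 of 100 gave at least 7, with up to 5 in the others. Of the 100 divisions, 13 part all 5 pairs of cultures, the real one among them. The others of these gave at most 0 genes by edgeR, 21 lists by camera and 0 by fry. A share of 1 in 13 is above 1 in 20, so these divisions cannot exclude chance at that share either.

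Libraries of mouse 3 had 1190 to 1376 CPM of Xist, the RNA of the inactive X chromosome, and at most 0.0358 CPM of the Y-linked gene Eif2s3y, while those of mice 1 and 2 had at most 1.20 CPM of Xist. Rps3a2 was at 4.65 to 5.59 CPM in mouse 1 and 154 to 171 CPM in mice 2 and 3, while Rps3a1, Rps3a2 and Rps3a3 together were at 873 to 999 CPM in all libraries. With mouse as a block, further macrophage genes chosen after their values were seen were higher in infected cultures, among them C1qb (46.2 ± 12.97 to 72.4 ± 12.2 CPM; edgeR adjusted p = 2.99e-06, and 0.326 without the block), Stab1 (109 ± 35.7 to 153 ± 38.1 CPM; 1.25e-05, and 0.769) and Marco, a scavenger receptor (1.68 ± 0.473 to 3.62 ± 1.39 CPM; 0.00024, and 0.120).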
